A study of Mus musculus with 24 samples.

How the data were processed

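RNA was measured in 24 libraries of mouse small intestinal organoids, which are epithelial cultures grown from intestinal crypts. The labels give 6 groups of 4 libraries: recombinant Slit3, a secreted guidance protein, at 10 ug/mL, or an anti-gD control, each for 3, 24 and 72 h. Per the labels, cDNA was made from 2 ng of total RNA with Smart-Seq v4, 150 pg of cDNA went into Nextera XT libraries, and single-end reads of 50 bases were sequenced on an Illumina NovaSeq. This kit does not mark the strand. The labels give the genotype as wild type, while the strain entry of every sample lists both a wild-type and an LDLR-knockout BL6 line, so which line supplied the cultures is not settled here.

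The deposited values are raw counts per Ensembl gene, and the table holds whole numbers from 0 with no scaling. Per the submitters' processing notes, the authors aligned the reads with GSNAP to GRCm38.p5. The counting tool, the annotation release and the strand setting are not given in the sources used here. The table held 52636 genes, of which 52489 matched a gene identifier of GENCODE release M21 on GRCm38 and 147 did not. Symbols and coordinates come from that release. All 24 columns matched a sample, and 0 columns of per-sample values were left out.

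Totals ranged from 28148857 to 42282207 counts per library. At this depth 3 counts over all libraries together equal 0.00365 CPM (counts scaled to library size), the level that a count of 0 allows with 95% confidence. Counting intervals and such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Where a control group had 0 counts, the fold is a lower bound against 3 counts over that group; where it had 1 to 3 counts, the ratio of the groups is given with its exact 95% interval.

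Genes were kept with edgeR's filterByExpr by group, which left 16722. All libraries entered 1 fit with 6 group means in edgeR 4.0.16 (R 4.3.3), with TMM factors, glmQLFit with robust estimation and quasi-likelihood F tests. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene is called where this value is under 0.05. CPM use the library sizes times the TMM factors and are given as mean ± SD of 4 libraries, and log2 fold changes with their standard error (SE). The comparisons were Slit3 against control at 3, 24 and 72 h, the average of these 3, a joint test of whether the Slit3 effect differed between times, and the controls at 24 h and at 72 h against those at 3 h. The fold changes at different times were also correlated across genes, which are not independent replicates.

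Before the data were examined, 30 gene lists were fixed, covering intestinal cell types, signalling, stress, metabolism, epithelial junctions and markers of other cell types (fibroblast, immune, endothelial, neuron and glia). All their members matched an identifier. Some lists share members, so their calls are not independent. Cd44 is in the stem cell and Wnt lists, and Myc in the Wnt and immediate early lists. Lists with at least 3 tested members were tested with cameraPR of limma 3.58.1 on the edgeR statistics with a preset correlation of 0.01, adjusted over the 29 lists tested, and again with camera and an estimated correlation. Members were also adjusted over the list alone. The named genes were fixed by a rule: among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries (for the average, group means that differ in the same direction at each time), without predicted-gene, clone or pseudogene names, the 10 largest changes in each direction. Of the fixed lists described, at most 4 members of smallest p are named. The interferon receptor and glucocorticoid lists of the closing section do not follow this rule. Slit3, Robo1, Robo2, Lgr5, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi and Mki67 were always reported. Further lists in the closing section were chosen after values were seen.

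The alternatives fixed in advance were DESeq2 1.42.0 with its default Wald test, limma-voom with sample quality weights, edgeR without robust estimation, DESeq2-type size factors (RLE), upper-quartile factors, no filter, a filter at a mean of 5 CPM, only the libraries compared, the replicate number as a block over all libraries or within each time, an estimated correlation in the list tests, and leaving out each library in turn. A fit without the library of each group with the highest mean chi-square against its replicates, 6 in all, was added after the data were seen. Other groupings of the libraries were run in 35 splits of 8 libraries or 100 random draws. The fits were tested on simulated data, with known changes added in 4 against 4 libraries at 3 h. For each fold 50 genes were changed, as many up as down. Of these, edgeR recovered 54% of 1.2-fold, 80% of 1.5-fold, 96% of 2-fold and 98% of 4-fold changes, with 4.09% false calls. The recovery was not split by expression level, so it may not hold for genes with few counts. The real Slit3 comparisons called far more genes, with more 2-fold rises than falls. The simulation does not cover that setting, so its rate of false calls may not hold there. Of 200 random lists tested in that simulation, 2.5% had an unadjusted cameraPR p under 0.05. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.788. The simulation therefore does not test the list calls made with the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

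How reads of overlapping genes were assigned is not stated, so the values of Irgm2 and Igtp, which overlap on the same strand, and of Pla2g5 and Pla2g2a, which overlap on opposite strands, are uncertain. Values of near-identical families (Ifit3 and Ifit3b, Oas, Gbp, Tgtp, immunity-related GTPases, defensins, Cyp2c, Ces, Ugt2b and H2 genes) are uncertain in how reads were divided among members. Nothing in the labels says whether the 4 libraries of a group come from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.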

Results

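Gene expression was measured by RNA sequencing in mouse small intestinal organoids given recombinant Slit3 at 10 ug/mL or an anti-gD control for 3, 24 or 72 h, with 4 libraries in each of the 6 groups. Slit3 is a secreted ligand of Robo receptors, best known from axon guidance. Each library held 28148857 to 42282207 counts, and 15141 to 16030 genes had at least 10 counts. Principal component 1 of the tested genes carried 46.02% of the variance. On it the 12 control libraries lay between -39.42 and -35.09, the Slit3 libraries at 3 h between 4.25 and 7.29, and those at 24 and 72 h between 46.54 and 58.33.

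The ligand and its receptors were near the limit of detection. Slit3 transcripts had 22 counts over all 24 libraries, Robo1 had 16, Robo2 had 73, Robo3 had 70 and Robo4 had 0, which allows up to 0.00365 CPM. Robo2 had 2 counts in controls and 5 in Slit3 libraries at 3 h, 11 and 39 at 24 h, and 0 and 16 at 72 h, too few for the test across genes. The labels name no check of the added protein, and transcript counts do not measure it.

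Markers of other cell types were low in every group. The summed CPM of 12 immune markers was 4.03 ± 0.384 (SD, n = 4) in controls and 4.76 ± 0.664 with Slit3 at 3 h, and 4.39 ± 0.476 and 3.37 ± 0.548 at 72 h. The 13 fibroblast markers summed to 5.33 ± 1.19 and 6.31 ± 0.534 CPM at 3 h, the 8 neuron and glia markers to 6.25 ± 0.536 and 4.28 ± 0.913, and the 8 endothelial markers to 0.787 and 0.708. Mitochondrial transcripts made up 0.227% ± 0.010 of counts in controls and 0.149% ± 0.015 with Slit3 at 24 h, and 0.235% ± 0.022 and 0.159% ± 0.015 at 72 h (n = 4 each), against 0.219% ± 0.022 and 0.205% ± 0.009 at 3 h. Ribosomal protein transcripts made up 0.4075% ± 0.00755 of counts in controls and 0.384% ± 0.00668 with Slit3 at 3 h, 0.41% ± 0.014 and 0.345% ± 0.0066 at 24 h, and 0.388% ± 0.012 and 0.3535% ± 0.00835 at 72 h (n = 4 each). The lower ribosomal protein share goes with every gene group described for Slit3 at the 3 times, and the lower mitochondrial share with those at 24 and 72 h.

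Comparing Slit3 with control at 3 h asks what differed early between the Slit3 preparation and the anti-gD control. Here and below, another ingredient of the preparation cannot be told apart from Slit3 itself. Antiviral genes induced by interferon rose most. Ifit3b, of a family of interferon-induced proteins that bind viral RNA, was at 49.9 ± 5.20 CPM (SD, n = 4) with Slit3 and 0.0611 ± 0.0706 in controls, 745-fold higher (log2 change 9.54 ± 0.22 SE; edgeR adjusted p = 1.08e-22). The gene ENSMUSG00000062488 lies on chromosome 19 from 34607970 to 34613401 (GRCm38). Ifit1 went from 2.46 ± 0.960 to 465 ± 41.2 CPM, 185-fold. The folds of Mx2, which blocks viral replication, Ifit3, Igtp, Rsad2 (viperin), Ifi44, Irgm2, Isg15, a ubiquitin-like modifier, and Rtp4 ran from 296 to 86.0.

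The genes with the largest decreases at 3 h changed far less. Igsf11, an adhesion molecule, fell to 6.63 ± 1.81 CPM from 13.2 ± 1.33 (log2 change -0.99 ± 0.14; edgeR adjusted p = 1.9e-06), and Arrdc3, an arrestin-like regulator of receptor trafficking, fell to 27.1 ± 2.05 from 50.3 ± 1.61. Tarsl2, N6amt1, Hmgxb4, Rbm4b, Pm20d2, Epc2, Sgk1 and Thg1l had log2 changes between -0.96 and -0.76.

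Of the fixed lists at 3 h, the interferon list stood apart: all 21 tested members rose (21 adjusted over the list alone), with a median log2 change of 4.39. Among them were Stat2, Stat1 and Irf9, which carry the interferon signal to the nucleus, at 2.77, 3.53 and 2.93, and the RNA sensor Dhx58 at 3.97. Its adjusted p was 5.53e-57 with the preset correlation and 6.64e-07 with an estimated correlation.

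Further lists were called at 3 h with the preset correlation only. Of 19 glycolysis and hypoxia genes, 14 rose, 0 fell and 5 were not called (16 up adjusted over the list alone), including Vegfa (0.52), Ldha (0.28), Hk2 (0.37) and Pfkp (0.45). The list's adjusted p was 6.44e-06, and adjusted p = 0.536 with an estimated correlation. Of 21 immediate early genes, 10 rose and 11 were not called (12 up adjusted over the list alone), among them Klf6 (0.59), Atf3 (1.09), Myc (0.32) and Dusp6 (0.66), with an adjusted p of 0.000349, and adjusted p = 0.165 with an estimated correlation. Of 24 proliferation genes, 8 fell and 16 were not called (10 down adjusted over the list alone), with Mcm5 of the replication helicase at -0.26 and the mitotic genes Ccna2, Ccnb2 and Cdc20 at -0.15, -0.16 and -0.14. That list had an adjusted p of 0.000548, and adjusted p = 0.165 with an estimated correlation. Of 16 junction genes, 9 rose and 7 were not called (9 up adjusted over the list alone), including F11r (0.38), Cldn15 (0.34), Cldn2 (0.17) and Cdh1 (0.13), with an adjusted p of 0.00121, and adjusted p = 0.165 with an estimated correlation.

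Of 23 enterocyte genes at 3 h, 7 rose and 16 were not called (7 up adjusted over the list alone), among them the glucose transporter Slc5a1 (0.32) and the brush border genes Anpep (0.61), Sis (0.38) and Vil1 (0.18). The list's adjusted p of 0.0122 became 0.241 without Slit3 3 h replicate 1, 0.0503 with a filter at 5 CPM and 0.124 with DESeq2, and was adjusted p = 0.752 with an estimated correlation. Of 12 NFkB and inflammation genes, 7 rose, 1 fell and 4 were not called (7 up and 1 down adjusted over the list alone), led by the chemokine Cxcl10 at 6.22, with Cxcl16 (0.53), Nfkb2 (0.29) and Nfkbia (0.16). The median of the list was 0.217, far below Cxcl10. That list's adjusted p of 0.0196 became 0.053 without control 3 h replicate 3, and was adjusted p = 0.296 with an estimated correlation.

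In all, edgeR called 4283 genes at 3 h, of which 2590 rose and 1693 fell, and 262 rose and 74 fell at least 2-fold. With upper-quartile scaling 43.1% of calls were higher, against 60.5%, so the balance of small changes at 3 h rests on the scaling. The number of lists called with the preset correlation, 7 of 29, was matched or passed by 17 of 35 splits of the same libraries, so chance is not excluded for that number.

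**Figure D1:**
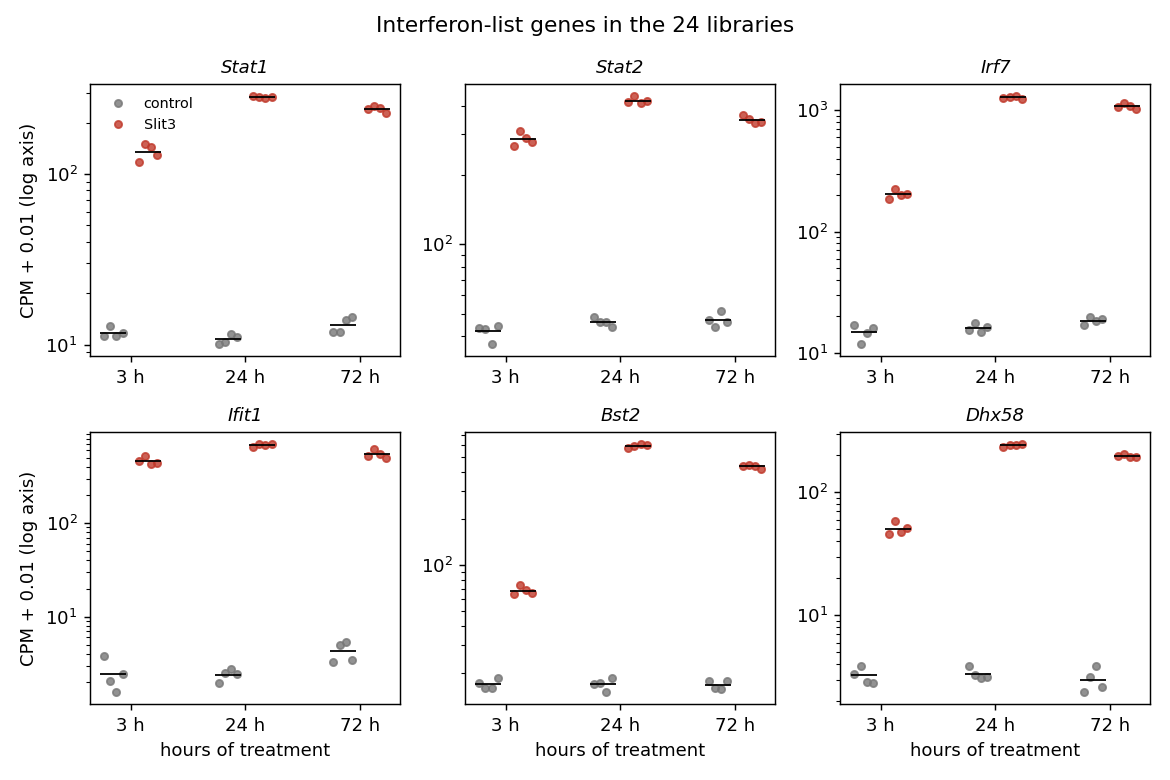
CPM plus 0.01, on a log axis, of 6 genes of the interferon list against hours of treatment, with 1 point per library (4 per group), controls in grey, Slit3 in red and a line at each group mean. At 3 h the Slit3 libraries averaged 465 CPM of Ifit1 and the controls 2.46, and in each panel every Slit3 library lies above every control library of its time.

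The comparison at 24 h asks what was changed after 1 day, and the interferon-induced genes were higher still than their controls. Ifit3 was at 761 ± 29.9 CPM (SD, n = 4) with Slit3 and 0.185 ± 0.108 in controls, a fitted 3937-fold (log2 change 11.94 ± 0.22; edgeR adjusted p = 4.87e-21). Iigp1, a GTPase that acts on the vacuoles of intracellular parasites, was at 29.6 ± 1.45 CPM and had 0 counts in controls, so it was at least 1399-fold higher (chromosome 18, 60376027 to 60392634). Tgtp2, a related GTPase, was at least 760.4-fold higher. Oas2, which makes the messenger that activates RNase L, had 3 control counts and a ratio of 8891 (95% counting interval 3042 to 43120). Gbp3, a guanylate-binding protein, had 1 control count and a ratio of 10880 (interval 1953 to 429900).

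Trim30a, Zbp1, a sensor of Z-form nucleic acid, Phf11d, Mx1 and Oas3 were 3217-fold to 1360-fold higher at 24 h. Lrat and Ces1d had the largest decreases. Lrat, which esterifies retinol, fell to 3.42 ± 0.880 CPM from 13.1 ± 1.80 (log2 change -1.94 ± 0.16; edgeR adjusted p = 2.18e-11), and the carboxylesterase Ces1d to 18.6 ± 1.14 from 68.7 ± 6.29. Ctrb1, a digestive protease, Cyp2c38, Mxd4, the antimicrobial lectin Reg3b, Abcc6, Abat, which breaks down GABA, Acaa1b and Ntn4 had log2 changes between -1.82 and -1.38.

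All 21 interferon genes rose at 24 h (21 adjusted over the list alone), with a median log2 change of 8.02, led in p by Bst2 (5.14), Dhx58 (6.18), Stat1 (4.71) and Stat2 (3.19). The list's adjusted p was 1.42e-47, and 3.03e-06 with an estimated correlation. Of 12 NFkB and inflammation genes, 11 rose and 1 was not called (11 up adjusted over the list alone), with Cxcl10 at 8.56, the inhibitor Nfkbia at 0.68, Cxcl16 at 1.90 and Tnf at 3.32. The NFkB list's adjusted p was 2.62e-09, and 0.00268 with an estimated correlation. Its median was 0.604, far below Cxcl10. Of 17 genes of the unfolded protein response, 15 rose, 1 fell and 1 was not called (15 up and 2 down adjusted over the list alone), among them the chaperone Hspa5 (0.52), Asns (0.59), Creld2 (0.74) and Sdf2l1 (0.73), with an adjusted p of 1.42e-10, and 0.00469 with an estimated correlation.

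Immediate early, actin and junction genes also rose as lists at 24 h. Of 21 immediate early genes, 13 rose, 1 fell and 7 were not called (13 up and 2 down adjusted over the list alone), including Klf6 (0.94), Myc (0.61), Fos (1.48) and Atf3 (1.67), with an adjusted p of 1.51e-05, and 0.0418 with an estimated correlation. Of 17 actin and SRF genes, 9 rose, 2 fell and 6 were not called (9 up and 2 down adjusted over the list alone), including Cnn2 (1.60), Tagln2 (0.57), Zyx (0.64) and Tpm4 (0.36), with an adjusted p of 0.00187, and 0.0108 with an estimated correlation. Of 16 junction genes, 12 rose, 2 fell and 2 were not called (12 up and 2 down adjusted over the list alone), including F11r (0.65), Cldn2 (0.60), Cldn15 (0.35) and Cldn7 (0.26), with an adjusted p of 2.91e-05, and 0.0236 with an estimated correlation.

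Called at 24 h with the preset correlation only were lists of cell types and repair. Of 17 YAP and regeneration genes, 10 rose and 7 were not called (11 up adjusted over the list alone), with Ly6a, also called Sca-1, at 5.55, the EGF receptor ligands Areg and Ereg at 1.91 and 2.74, and Amotl2 at 1.19. The adjusted p was 4.19e-05, and adjusted p = 0.0869 with an estimated correlation. The median of the list was 0.627, far below Ly6a. Whether Ly6a here and Cxcl10 in the NFkB list rose as part of the interferon response was not tested. Of 14 Paneth cell genes, 11 fell, 1 rose and 2 were not called (11 down and 1 up adjusted over the list alone), with Itln1 at -0.52, Habp2 at -0.69 and the defensin Defa17 at -0.35, and with Nupr1, a stress-induced nuclear protein, at 0.73. That list had an adjusted p of 0.00187, and adjusted p = 0.395 with an estimated correlation. Of 18 stem cell genes, 8 fell, 2 rose and 8 were not called (8 down and 2 up adjusted over the list alone), with Lgr5 and Smoc2 both at -0.47, Rgmb at -0.22 and Cd44 at 0.52. Its adjusted p of 0.0267 became 0.0821 with a filter at 5 CPM and 0.127 with DESeq2, and was adjusted p = 0.445 with an estimated correlation.

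Of 16 goblet cell genes at 24 h, 8 fell and 8 were not called (8 down and 1 up adjusted over the list alone), including Tff3 (-0.30), Spink4 (-0.42), Fcgbp (-0.62) and Tpsg1 (-0.61). The adjusted p of 0.0393 became 0.0695 without control 24 h replicate 3, 0.0546 without Slit3 24 h replicate 1 and 0.0541 without Slit3 24 h replicate 2, and 0.064, 0.168 and 0.13 with upper-quartile scaling, a filter at 5 CPM and DESeq2, and was adjusted p = 0.386 with an estimated correlation. Of 6 MHC class II genes, 3 rose and 3 were not called (4 up adjusted over the list alone), with the invariant chain Cd74 at 3.47 and H2-Ab1 at 1.40. The adjusted p of 0.0429 became 0.0529 and 0.0584 without control 24 h replicates 3 and 4 and 0.0764 without Slit3 24 h replicate 1, 0.0507 with the replicate block, 0.0612 with limma-voom and 0.236 with DESeq2, and was adjusted p = 0.227 with an estimated correlation.

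At 24 h edgeR called 6214 genes, of which 3154 rose and 3060 fell, and 607 rose and 203 fell at least 2-fold. Upper-quartile scaling gave 39.2% of calls higher, against 50.8%. The preset correlation called 11 of 29 lists. In all 6 of 35 splits called as many, the real 1 included, but the other 5 kept 3 of the 4 Slit3 libraries together and with them part of the effect. The 18 splits with 2 Slit3 libraries on each side called at most 5 lists, and are too few to decide about chance.

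The comparison at 72 h asks what was changed after 3 days. Interferon-induced genes had the largest increases at this time too, and Ctrb1 and Reg3b the largest decreases. Ctrb1, the precursor of the protease chymotrypsin, was at 1.06 ± 0.319 CPM (SD, n = 4) with Slit3 and 11.2 ± 0.965 in controls (log2 change -3.40 ± 0.18; edgeR adjusted p = 4.58e-16; chromosome 8, 111686519 to 111691010). Reg3b, an antimicrobial lectin, was at 3.40 ± 0.595 and 35.0 ± 4.96 CPM (log2 change -3.37 ± 0.21; edgeR adjusted p = 5.04e-12; chromosome 6, 78370657 to 78373466). Ifi27l2a, an interferon-induced mitochondrial protein, was at 558 ± 26.5 CPM with Slit3 and 0.153 ± 0.0506 in controls, a fitted 3636-fold.

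Gbp3, Iigp1 and Tgtp2 had 0 control counts at 72 h and were at least 2954-fold, 1165-fold and 609.8-fold higher. Oas2, Zbp1 and Phf11d had 2 control counts each and ratios of 13940 (95% counting interval 3860 to 115100), 7302 (2021 to 60300) and 6361 (1760 to 52530). Nlrc5, the activator of MHC class I genes, had 3 control counts and a ratio of 1262 (431.7 to 6125). Ifi44 and Oas3 were 1348-fold and 914.2-fold higher. The other large decreases were Ugt2b5, a glucuronidation enzyme, at -2.64, Ces1d at -2.56, the iron reductase Cybrd1 at -2.38, Mt4, Cyp2c37, the alkaline phosphatase Akp3, Agtpbp1 and Slc6a3, the last 5 between -2.22 and -1.83.

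**Figure D2:**
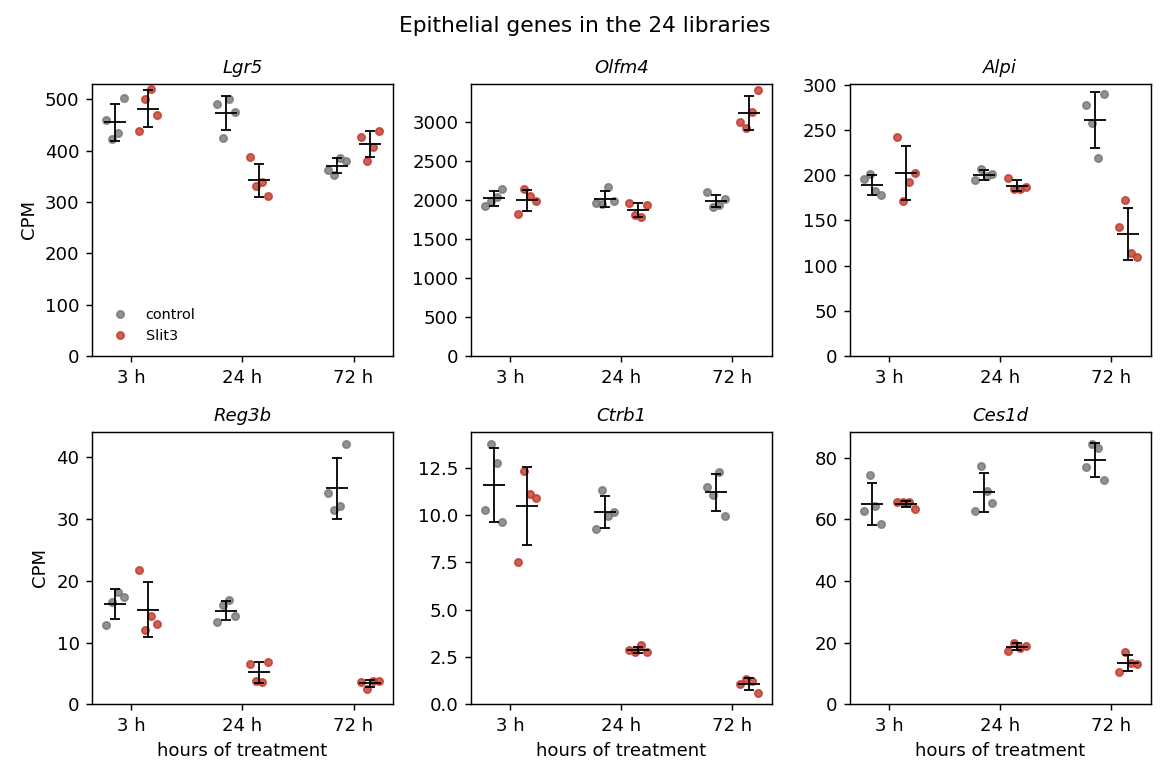
CPM of 6 epithelial genes against hours of treatment, with 1 point per library (4 per group), controls in grey, Slit3 in red, and lines for the mean and SD of each group. At 72 h Olfm4 averaged 3111 CPM with Slit3 and 1986 in controls, and Reg3b 3.40 and 35.0.

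All 21 interferon genes rose at 72 h (21 adjusted over the list alone), with a median log2 change of 7.10 and Bst2 (4.70), Dhx58 (6.06), Stat1 (4.20) and Irf7 (5.88) smallest in p. The list's adjusted p was 1.01e-51, and 1.75e-06 with an estimated correlation. Of 12 NFkB and inflammation genes, 10 rose and 2 were not called (10 up adjusted over the list alone), with Cxcl10 at 6.12, Cxcl16 at 1.78, Nfkbia at 0.43 and Nfkb2 at 0.49, an adjusted p of 7.09e-08, and 0.00423 with an estimated correlation. The median of the list was 0.411. Of 17 actin and SRF genes, 11 rose and 6 were not called (13 up adjusted over the list alone), with Tagln2 at 0.55, Acta1 at 1.12, Zyx at 0.58 and Cnn2 at 0.84, an adjusted p of 8.26e-06, and 0.000786 with an estimated correlation. Of 16 junction genes, 11 rose, 1 fell and 4 were not called (11 up and 1 down adjusted over the list alone), with F11r at 0.51, Cldn2 at 0.54, Cdh1 at 0.39 and Cldn4 at 1.26, an adjusted p of 1.62e-05, and 0.0266 with an estimated correlation.

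Stem cell, Wnt and repair lists were higher at 72 h with the preset correlation only. The stem cell and Wnt lists share members, Cd44 among them, and are not separate evidence. Of 18 Wnt targets, 12 rose and 6 were not called (15 up adjusted over the list alone), including Myc (0.44), Apcdd1 (0.88), Cd44 (0.57) and Prox1 (1.14), with an adjusted p of 7.42e-06, and adjusted p = 0.0791 with an estimated correlation. Of 18 stem cell genes, 12 rose, 2 fell and 4 were not called (13 up and 2 down adjusted over the list alone), including Olfm4 (0.65), Tnfrsf19 (0.93), Cd44 and Lrig1 (0.28), with an adjusted p of 0.000327, and adjusted p = 0.247 with an estimated correlation. Of 17 YAP and regeneration genes, 11 rose and 6 were not called (11 up and 1 down adjusted over the list alone), with Ly6a at 5.85, Amotl2 at 1.41, Areg at 1.26 and Ereg at 2.64, an adjusted p of 1.62e-05, and adjusted p = 0.0791 with an estimated correlation. The median of the list was 0.641. Of 14 Paneth cell genes, 7 rose, 2 fell and 5 were not called (8 up and 2 down adjusted over the list alone), including Ang4 (0.88), Mmp7 (0.45), Defa3 (0.87) and Nupr1 (0.45). That list's adjusted p of 0.0163 became 0.0543 without Slit3 72 h replicate 4, and was adjusted p = 0.464 with an estimated correlation.

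Metabolic lists were lower at 72 h, again with the preset correlation only. Of 20 cholesterol synthesis genes, 18 fell and 2 were not called (18 down adjusted over the list alone), including the sterol carrier Stard4 (-0.37), Lss (-0.52), Sc5d (-0.35) and Dhcr7 (-0.30), with an adjusted p of 1.27e-08, and adjusted p = 0.186 with an estimated correlation. Of 19 glycolysis and hypoxia genes, 13 fell, 1 rose and 5 were not called (13 down and 1 up adjusted over the list alone), with Ndrg1 at -1.11, Pdk1 at -0.70, Car9 at -0.55 and Hk2 at 0.58, an adjusted p of 0.000327, and adjusted p = 0.464 with an estimated correlation. Of 14 genes of the NRF2 oxidative stress response, 8 fell, 2 rose and 4 were not called (8 down and 2 up adjusted over the list alone), with Gsta3 at -1.21, Nqo1 at -1.41, Gclm at -0.38 and Gstm1 at -1.19, an adjusted p of 0.0027, and adjusted p = 0.314 with an estimated correlation. Of 18 fatty acid oxidation genes, 9 fell, 3 rose and 6 were not called (11 down and 4 up adjusted over the list alone), with Acox1 at -0.78, Acot1 at -0.55, Acaa2 at -0.42 and Acadl at 0.77. Its adjusted p of 0.0201 became 0.0639 without Slit3 72 h replicate 4, and was adjusted p = 0.464 with an estimated correlation.

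Defence and stress lists were mixed at 72 h. Of 12 epithelial defence genes, 8 rose, 1 fell and 3 were not called (8 up and 2 down adjusted over the list alone), with Pglyrp1, which binds bacterial peptidoglycan, at 0.78, Pla2g5 at 0.93, Duoxa2, the maturation factor of a hydrogen peroxide-making oxidase, at 2.00, and Reg3b at -3.37. Its adjusted p of 0.00617 became 0.262 with a filter at 5 CPM and 0.0526 with DESeq2, and was adjusted p = 0.0791 with an estimated correlation. Of 17 genes of the unfolded protein response, 10 rose, 4 fell and 3 were not called (10 up and 4 down adjusted over the list alone), with Asns at 0.37, Sdf2l1 at 0.40, Chac1 at 1.06 and Xbp1 at -0.30. Its adjusted p of 0.0333 became 0.053 and 0.0731 without control 72 h replicates 1 and 4, 0.0528, 0.0555, 0.13 and 0.0814 with upper-quartile scaling, a filter at 5 CPM, DESeq2 and only the libraries compared, and was adjusted p = 0.322 with an estimated correlation. Of 21 immediate early genes, 8 rose, 2 fell and 11 were not called (9 up and 3 down adjusted over the list alone), with Myc at 0.44, Klf6 at 0.54, Jun at 0.61 and Junb at 0.57. Its adjusted p of 0.0452 became 0.0534 and 0.0765 without control 72 h replicates 2 and 4, 0.0539 and 0.0543 without Slit3 72 h replicates 2 and 4 and 0.0507 with the replicate block, 0.0555, 0.11 and 0.0614 with a filter at 5 CPM, DESeq2 and only the libraries compared, and was adjusted p = 0.37 with an estimated correlation.

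At 72 h edgeR called 5696 genes, of which 2916 rose and 2780 fell, and 611 rose and 232 fell at least 2-fold. Upper-quartile scaling gave 43.8% of calls higher, 2529 against 3247 lower. The preset correlation called 15 of 29 lists. The 2 other splits of 35 that called as many kept 3 of the 4 Slit3 libraries together, and the 18 with 2 on each side called at most 10, so these splits do not decide about chance.

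Other fixed lists were not called at any time against control (adjusted p from 0.0597 to 1). Of 23 enteroendocrine genes, 1 rose and 2 fell at 3 h, 2 and 7 at 24 h, and 11 and 3 at 72 h, where the hormone genes Nts, Cck and Ghrl were at 1.31, 0.48 and -0.72. Of 10 tuft cell genes, 3 fell at 24 h and 1 at 72 h, and of 6 M cell genes 2 fell at 3 h, 2 rose and 1 fell at 24 h, and 1 rose and 1 fell at 72 h. Of 13 Notch genes, 5, 6 and 3 fell and 1, 2 and 2 rose at 3, 24 and 72 h. Of 9 BMP targets, 3, 3 and 0 rose and 2, 2 and 1 fell. Of 16 Slit and Robo pathway genes, 3, 1 and 1 rose and 0, 5 and 3 fell. Of 14 p53 targets, 5, 7 and 3 rose and 3, 3 and 6 fell. The 2 tested endothelial markers were too few for a list test. Of the tested markers of other cell types 0 were called at 3 h, and the macrophage lysozyme Lyz2 was at -1.17 at 24 h (edgeR adjusted p = 0.00257). At 72 h the fibroblast receptor Pdgfrb was at 0.81 and the endothelial receptor Tek at 2.98, with Lyz2 at -0.75 (edgeR adjusted p 0.0271, 0.036 and 0.0465). The call of Pdgfrb ended without control 72 h replicates 1 or 3 (0.11 and 0.0734) or Slit3 72 h replicate 3 (0.156), with limma-voom (0.0557) and with the replicate block within each time (0.0566). That of Tek ended without control 72 h replicates 1, 2 or 4 (0.0518, 0.0884 and 0.105) or Slit3 72 h replicate 1 (0.121). That of Lyz2 ended without control 72 h replicates 1, 2 or 4 (0.129, 0.0771 and 0.0542) or Slit3 72 h replicates 1, 2 or 4 (0.119, 0.159 and 0.11), and with only the libraries compared (0.0521).

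**Figure D3:**
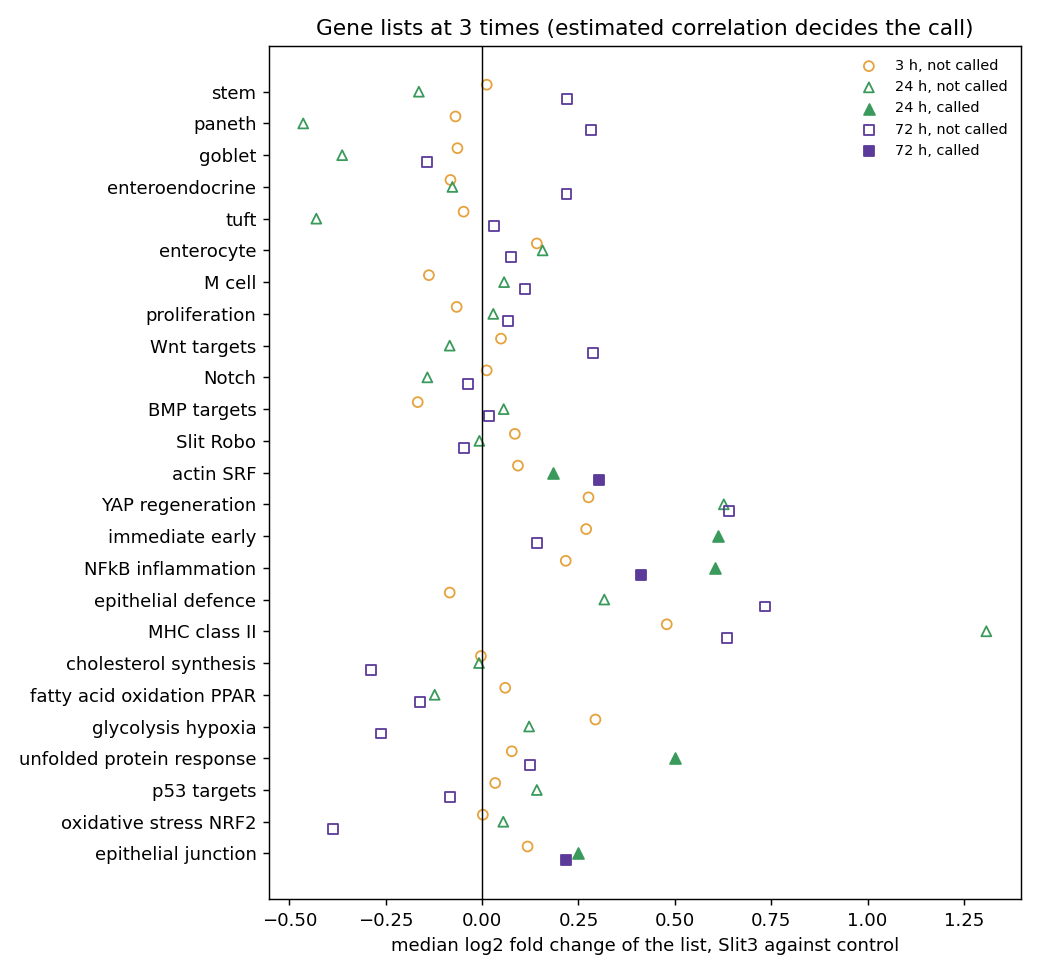
Median log2 fold change of each of 25 fixed lists of epithelial cell types and pathways, Slit3 against control, with 1 symbol per time and a filled symbol where the list was called with an estimated correlation. The interferon list, with medians of 4.39, 8.02 and 7.10, and the lists of other cell types are not drawn.

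Averaged over the 3 times, with 12 libraries on each side, interferon-induced genes had the largest increases. Oas2, Ifit3, Phf11d, Ifit3b, Zbp1, Ifi44 and Trim30a were 1201-fold to 500.8-fold higher. Gbp3 had 1 control count over all times and Tgtp2 and Iigp1 had 0, so no averaged fold is given for these 3 genes. With Slit3 they had 261, 109 and 3 counts at 3 h. The adjusted p of Iigp1, 9.43e-07, became 1 without Slit3 3 h replicate 1. Ctrb1 (-1.79), Reg3b (-1.67), Ugt2b5 (-1.28), Lrat (-1.25), Cyp2c37 (-1.17), Cpm, Abat, Agtpbp1, Mxd4 and Acaa1b (-0.94) had the largest decreases (edgeR adjusted p at most 2.27e-10).

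On average 21 of 21 interferon genes rose (21 adjusted over the list alone), 11 of 12 NFkB genes rose, 12 of 17 actin genes rose and 1 fell, 12 of 16 junction genes rose and 2 fell, and 14 of 17 genes of the unfolded protein response rose and 2 fell. Their adjusted p with an estimated correlation was 5.12e-06, 0.00316, 0.00316, 0.0142 and 0.0389. With the preset correlation only, 11 of 17 YAP genes rose (adjusted p 3.69e-05, and adjusted p = 0.0845 with an estimated correlation) and 14 of 21 immediate early genes rose and 2 fell (8.41e-05, and adjusted p = 0.0745 with an estimated correlation). Of 20 cholesterol genes, 13 fell (0.000921, and adjusted p = 0.605 with an estimated correlation). Of 6 MHC class II genes, 5 rose (0.0433, and adjusted p = 0.156 with an estimated correlation), a call that ended without Slit3 3 h replicates 2 or 3 (0.0541 and 0.053) and with DESeq2 or limma-voom (0.212 and 0.051). In all 7467 genes were called, 3760 higher and 3707 lower, or 37.7% higher in place of 50.4% with upper-quartile scaling. As many lists as the 9 called were found in 34 of 100 random regroupings, the real grouping included, but the 12 regroupings with 2 Slit3 libraries on each side at each time called at most 7. The other 33 keep part of the effect at some time, so these regroupings do not decide about chance.

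The joint test asks whether the effect of Slit3 differed between times. It did for 5706 of 16722 genes, with 4559 genes differing between 72 and 3 h, 4315 between 24 and 3 h and 1834 between 72 and 24 h. Of the genes called at each time, 938 rose at all 3 and 350 fell at all 3, out of 1710 called at every time. Across genes the log2 fold changes correlated with a Pearson r of 0.652 between 3 and 24 h, 0.585 between 3 and 72 h and 0.833 between 24 and 72 h (Spearman rho 0.285, 0.155 and 0.543). Genes are not independent replicates, and without those changed at least 2-fold r was 0.23, 0.109 and 0.454. Of genes called at both times, 79.5%, 68.7% and 96.1% moved in the same direction.

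**Figure D4:**
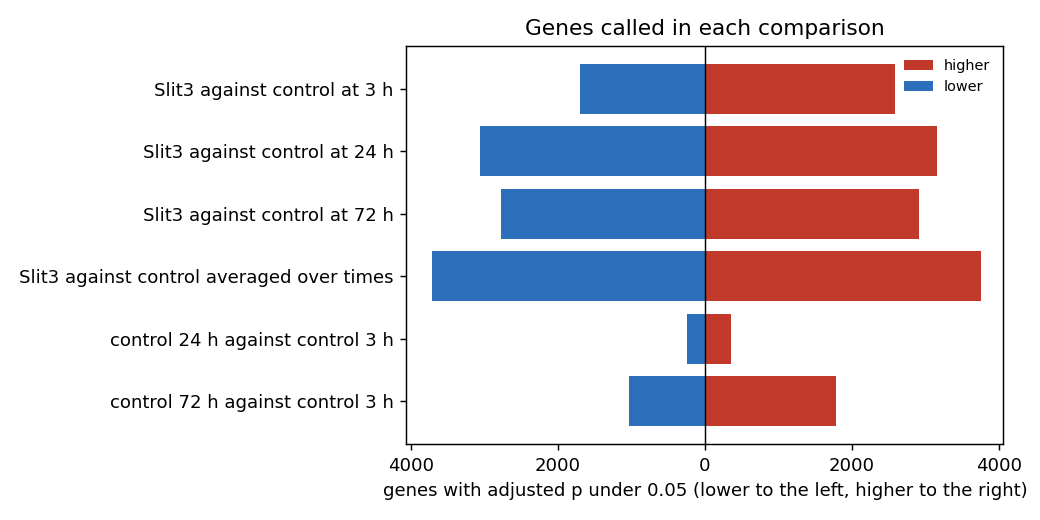
Number of genes called by edgeR in each comparison, with higher genes to the right in red and lower genes to the left in blue. The Slit3 comparisons called 4283 to 7467 genes, the controls 592 at 24 h and 2811 at 72 h.

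The control libraries give the background of culture time. At 72 h against 3 h, Fkbp5, a chaperone partner of the glucocorticoid receptor, fell to 35.5 ± 2.71 CPM from 199 ± 23.4 (SD, n = 4; log2 change -2.49 ± 0.07; edgeR adjusted p = 2.34e-19; chromosome 17, 28399094 to 28517527). Reg3a, an antimicrobial lectin, rose to 30.3 ± 1.12 from 8.44 ± 1.61 CPM, 3.60-fold (edgeR adjusted p = 1.7e-11), and G6pc, the last enzyme of glucose production, rose to 140 ± 6.70 from 54.3 ± 2.35. Mbl2, Adh4, Id3, Reg3b, Slc13a1, Atf3, Cfhr2 and Slc28a1 were 2.59-fold to 1.95-fold higher. Cyp1a1, an enzyme induced through the aryl hydrocarbon receptor, Hif3a, the ketone body enzyme Hmgcs2, Arhgef40, the clock gene Per1, Cyp27a1, Pla2g2a, Pla2g5 and Defa3 had log2 changes between -2.02 and -0.95.

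Stem cell, Wnt and Paneth cell lists were lower in controls at 72 h than at 3 h, with the preset correlation only. Because the stem cell and Wnt lists share members, their falls are not separate evidence. Of 18 stem cell genes, 9 fell and 9 were not called (10 down adjusted over the list alone), including Tnfrsf19 (-0.70), Rnf43 (-0.32), Lrig1 (-0.26) and Sox9 (-0.25), with an adjusted p of 2.06e-07, and adjusted p = 0.162 with an estimated correlation. Of 18 Wnt targets, 8 fell, 1 rose and 9 were not called (11 down and 1 up adjusted over the list alone), with Myc at -0.30 and Sp5 at -0.56, an adjusted p of 1.8e-07, and adjusted p = 0.0944 with an estimated correlation. Of 14 Paneth cell genes, 8 fell, 1 rose and 5 were not called (8 down and 1 up adjusted over the list alone), with Defa3 at -0.95, Mmp7 at -0.40, Defa22 at -0.82 and Nupr1 at 0.64, an adjusted p of 9.62e-05, and adjusted p = 0.397 with an estimated correlation.

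Enterocyte and glycolysis lists were higher in controls at 72 h than at 3 h. The actin, cholesterol and junction lists moved less by their medians. All 5 were called with the preset correlation only. The BMP targets moved more, with a median log2 change of 0.49, but were not called (cameraPR adjusted p = 0.0893). Of 23 enterocyte genes, 10 rose, 1 fell and 12 were not called (10 up and 1 down adjusted over the list alone), with Aldob at 0.65, Dgat1 at 0.34, Fabp1 at 0.62 and Ada at -0.34, an adjusted p of 0.000217, and adjusted p = 0.515 with an estimated correlation. Of 19 glycolysis and hypoxia genes, 9 rose and 10 were not called (11 up adjusted over the list alone), with Ldha at 0.28, an adjusted p of 0.000217, and adjusted p = 0.608 with an estimated correlation. Of 17 actin and SRF genes, 4 fell (4 adjusted over the list alone), including Acta1 (-0.73) and Myh9 (-0.41), with an adjusted p of 0.0058, and adjusted p = 0.0572 with an estimated correlation. Of 20 cholesterol genes, 6 rose and 1 fell (8 up and 2 down adjusted over the list alone), including Sc5d (0.29) and Mvd (0.25). The adjusted p of 0.0364 became 0.102 and 0.317 without control 3 h replicates 2 and 3 and 0.166 and 0.269 without control 72 h replicates 2 and 3, and 0.0609, 0.13 and 0.115 with upper-quartile scaling, a filter at 5 CPM and only the libraries compared, and was adjusted p = 0.665 with an estimated correlation. Of 16 junction genes, 5 fell and 1 rose (5 down and 1 up adjusted over the list alone), including Cldn2 (-0.32) and Cldn15 (0.36). That adjusted p of 0.0364 became 0.0509 without control 72 h replicate 1, and was adjusted p = 0.397 with an estimated correlation.

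Of the 21 interferon genes, 4 rose and 1 fell in controls between 3 and 72 h (adjusted p = 0.671). Between 3 and 72 h edgeR called 2811 control genes, 1778 higher and 1033 lower. Between 3 and 24 h it called 592, 351 higher and 241 lower, of which 11 rose and 10 fell at least 2-fold, and the count was 339 and 385 without control 3 h replicates 2 and 3, 350 without control 24 h replicate 4 and 899 with DESeq2. Chance is not excluded for the 8 lists called at 72 h, matched or passed by 7 of 35 splits. The median, the mean and the test of a list differed in sign only for lists that were not called. These were tuft, M cell, interferon (0.073, -0.202 and up), NFkB, fatty acid, unfolded protein response (-0.003, 0.154 and up) and NRF2 genes in controls at 72 h. With Slit3 they were stem cell (0.012, -0.009 and down), tuft, Notch, BMP (-0.167, 0.124 and up) and epithelial defence genes at 3 h, M cell and BMP genes at 24 h, and tuft, M cell, Notch and BMP genes at 72 h. For the average they were enteroendocrine, proliferation, Notch and Slit and Robo genes.

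Among the epithelial genes fixed for reporting, Lgr5, the receptor that marks crypt stem cells, was at 482 ± 35.7 CPM with Slit3 and 455 ± 35.4 in controls at 3 h (log2 change 0.08; edgeR adjusted p = 0.424), fell to 343 ± 32.4 from 474 ± 33.9 at 24 h (-0.47; 5.25e-06), and was at 414 ± 25.5 and 371 ± 15.2 at 72 h (0.16; 0.0758, 0.0354 without Slit3 72 h replicate 2 and 0.0104 with only the libraries compared). Olfm4, also expressed in stem cells, had log2 changes of -0.02, -0.11 and 0.65 at the 3 times (edgeR adjusted p 0.843, 0.0984 and 3.62e-11), with 3111 ± 215 CPM against 1986 ± 82.7 at 72 h. At 24 h it was called with upper-quartile scaling (0.0166) and with only the libraries compared (0.0331), as was Alpi with the latter (0.0405). The brush border phosphatase Alpi was at 0.09, -0.09 and -0.96 (0.626, 0.606 and 2.08e-06) and fell to 135 ± 28.9 from 261 ± 30.9 CPM at 72 h. The Paneth cell lysozyme Lyz1 fell at 24 h (-0.26; 0.000102), with 0.01 and -0.06 at the other times (0.913 and 0.354). The goblet cell mucin Muc2 fell at 24 h (-0.65; 0.00229), with -0.12 and -0.09 at the others (0.642 and 0.706).

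The enteroendocrine granule protein Chga was at -0.12, -0.15 and 0.22 at 3, 24 and 72 h (edgeR adjusted p 0.148, 0.044 and 0.00501). Its call at 24 h ended without control 24 h replicates 2, 3 or 4 (0.0816, 0.0828 and 0.0815) or Slit3 24 h replicates 1 or 4 (0.0949 and 0.205), with no filter (0.118) and with the replicate block within each time (0.0511), and at 3 h it was called without Slit3 3 h replicate 3 (0.0423). The tuft cell kinase Dclk1 was at 0.50, -0.69 and 0.30 (0.378, 0.207 and 0.603). The proliferation marker Mki67 fell at 3 h (-0.22; 0.0148, and 0.0744 with no filter) and was at -0.13 and -0.04 later (0.134 and 0.662), with a call at 24 h without Slit3 24 h replicate 1 (0.0128), with the replicate block within each time (0.0274) and with upper-quartile scaling (0.0357). In controls from 3 to 72 h, Lgr5 fell (-0.30; 0.0032), Chga fell (-0.36; 7.11e-05), Mki67 fell (-0.25; 0.00821) and Alpi rose (0.46; 0.00902).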

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

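Of the tests in this part, only those of gene length, GC content and expression level and of variation between cultures in the glycolysis list were set down before their result was seen; the others, the splits of the libraries included, were set down only after it.

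The interferon-stimulated genes were higher with Slit3 at each time, in all 21 members of the list. Immune cells carried in the treated cultures stay open at 3 h. The summed CPM of 12 immune markers, only 3 of which were abundant enough to test, was then 4.761 ± 0.664 with Slit3. This is within its spread of the control mean plus 2 SD of 4.795. At 24 and 72 h the sum was 3.82 ± 0.28 and 3.37 ± 0.548, against 4.47 ± 0.746 and 4.39 ± 0.476 in controls. With 2 SD added, the Slit3 sums reached 4.378 and 4.47, under the control mean plus 2 SD of 5.964 and 5.345. These values argue against more immune cells with Slit3 at 24 and 72 h. Interferon transcripts made by the organoids also stay open: the 12 Slit3 libraries held 29 interferon counts, 17 against 5 in controls at 24 h (ratio 3.708, 95% counting interval 1.313 to 12.85), 5 against 0 at 3 h and 7 against 2 at 72 h. Another ingredient of the Slit3 preparation cannot be told apart from Slit3 itself, because no treated library is labelled with a different preparation. The receptor transcripts were sparse (89 counts of Robo1 and Robo2 over all libraries). A response to Slit3 itself may account for the pattern, and no library labelled as lacking Robo receptors or given another batch of protein is there to test it.

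Of 19 glycolysis and hypoxia genes, 14 rose with Slit3 at 3 h, and at 72 h 13 fell and Hk2 rose; the median of the differences was -0.604, and the effect was lower at 72 h than at 3 h for 17 genes and higher for 0 by the test of each gene. Scaling of the libraries is argued against, since the list medians differed by at least 0.54 in size under 3 scalings, and so are gene length, GC content and expression level, since 0 of 10000 matched lists had a median as low (lowest -0.308), a share printed as 1e-04, the smallest they can give. For variation between cultures shared by the whole list, the libraries were regrouped within each time. The difference of score differences was -0.675 (exact two-sided permutation p = 0.000408 over 4900 regroupings, the smallest they can give, not adjusted over the lists). This exceeds the spread between libraries. It does not decide about cultures, because the labels do not say whether the libraries of a group are separate cultures. With an estimated correlation, however, no call of the list held (adjusted p 0.536 at 3 h, 0.464 at 72 h and 0.271 for the difference), and the control scores at 3 h had an SD of 0.179 against 0.035 with Slit3. The controls also moved with time, with mean scores of 7.351, 7.791 and 7.573 at 3, 24 and 72 h. With Slit3 the means were 7.699, 7.892 and 7.247, so the Slit3 mean at 3 h lay below the control mean at 24 h. At 24 h 5 genes rose and 2 fell with Slit3, and the list was not called (cameraPR adjusted p = 0.237). The rise at 3 h is thus a rise over the lowest control mean. A handling step that differed between the 6 groups remains a possible explanation that the design cannot test.

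The Slit3 effect differed between times for 5706 genes by the joint test. Of the 20 genes named in each comparison, 15 at 3 h, 17 at 24 h, 16 at 72 h and 16 for the average had an effect that differed between times. Among the fixed genes, the log2 effect at 72 h minus that at 3 h was 0.0761 for Lgr5, 0.6656 for Olfm4, -0.0723 for Lyz1, 0.3389 for Chga and -1.0496 for Alpi (joint adjusted p 2.2e-05, 3.64e-09, 0.00789, 0.00128 and 9.99e-05). For Lgr5 and Lyz1 the difference between 24 and 3 h, -0.55 and -0.27, was larger in size than that between 72 and 3 h.

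List medians of the effect at 72 h minus 3 h differed by the list test with a preset correlation. They were 0.17 for stem cell genes, 0.348 for Paneth cell, 0.351 for enteroendocrine, 0.142 for proliferation, 0.17 for Wnt, 0.158 for actin, 0.417 for YAP, 1.73 for interferon, 0.329 for NFkB, 0.853 for epithelial defence and 0.11 for junction genes. They were -0.202 for cholesterol, -0.224 for fatty acid oxidation, -0.604 for glycolysis, -0.138 for p53 and -0.384 for NRF2 genes. With an estimated correlation only the interferon and actin differences were called (adjusted p 0.00763 and 0.0315).

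Single libraries lay far from the other 3 of their group in 8 of 176 groups of values, where chance alone gives about 8.8. The ribosomal protein share was 0.374% in Slit3 3 h replicate 2 (others 0.387 to 0.388) and 0.406% in control 72 h replicate 3 (others 0.381 to 0.383). In CPM, Lyz1 was 2196 in Slit3 3 h replicate 2 (others 2091 to 2103), Alpi 197.3 in Slit3 24 h replicate 1 (184.8 to 186.6), Pm20d2 8.393 in control 3 h replicate 2 (11.68 to 12.13), Epc2 5.024 in Slit3 3 h replicate 4 (3.455 to 3.711), Ifi44 351.2 in Slit3 72 h replicate 3 (332.8 to 334.5) and Reg3b 2.507 in Slit3 72 h replicate 2 (3.647 to 3.719).

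A chance division of these libraries into groups is argued against for the numbers of genes called. The real split was the only 1 of 35 to call as many at 3 h (4283, highest other 1), 24 h (6214, highest other 1), 72 h (5696, highest other 6), for controls at 24 h (592, highest other 10) and at 72 h (2811, highest other 61), and the only 1 of 100 for the average (7467, highest other 1741) and the difference between times (5706, highest other 4309). Such a division is also argued against for the correlations between times, 0.652, 0.585 and 0.833 against highest others of 0.328, 0.348 and 0.525 (1 of 100). Splits that mix the groups put the difference between groups into the spread within them. A difference between cultures that goes with the groups would also leave the real split alone, and these splits do not test it. Chance cannot be excluded for the numbers of lists called with the preset correlation at 3 h and in controls at 72 h. At 3 h 7 lists were called, and 17 of 35 splits called as many (highest other 12). In controls 8 were called, and 7 of 35 called as many (highest other 9). The splits leave chance undecided for the 11 lists at 24 h (6 of 35, highest other 13) and the 15 at 72 h (3 of 35, highest other 15). They also leave it undecided for the 9 lists of the average (34 of 100, highest other 15). The others that called as many kept more Slit3 libraries on 1 side than on the other (for the average, at some time), and with them part of the effect. This sorting of the splits was made after they were seen. Those with 2 on each side (at each time for the average) called at most 5, 10 and 7 lists.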

How the results depend on the processing

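The fit without 6 doubted libraries was chosen after the data were seen; the other alternatives were planned. In the counts of genes, every alternative stayed within 1.5 times the reported count, except for controls at 24 h against 3 h: 592 became 899 with DESeq2, 339 and 385 without control 3 h replicates 2 and 3 and 350 without control 24 h replicate 4, and the cause was not tested. Leaving out 1 library gave 3663 to 3980 genes at 3 h, 5664 to 5925 at 24 h, 5160 to 5470 at 72 h, 7280 to 7525 for the average, 5354 to 5688 for the difference between times, 339 to 705 for controls at 24 h and 2227 to 2428 at 72 h, and 6 to 7, 9 to 11, 12 to 16, 8 to 10 and 7 to 10 called lists at 3, 24 and 72 h, for the average and for controls at 72 h. With an estimated correlation, the lists called fell to 1, 6, 4, 5 and 0 under camera, which also uses its own statistics in place of those of edgeR, so the fall cannot be put down to the correlation alone and the cause was not tested. Without the doubted libraries 3919, 5911, 5299, 7115, 5206, 763 and 2450 genes and 7, 11, 14, 8 and 11 lists were called.

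The correlations of fold changes between times were 0.842, 0.79 and 0.947 with a filter at a mean of 5 CPM, which tests fewer genes. They ran from 0.587 to 0.627 (3 and 24 h), 0.534 to 0.566 (3 and 72 h) and 0.8 to 0.82 (24 and 72 h) when 1 library was left out, were lowest without Slit3 3 h replicate 1 (0.587, and 0.597 without replicate 2) and Slit3 3 h replicate 2 (0.534), and were 0.591, 0.557 and 0.808 without the doubted libraries. The cause was not tested.

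Whether equal replicate numbers pair libraries is not stated. Deviations from the group means correlated at -0.079 to 0.165 between same-numbered libraries and at -0.145 to 0.127 between the others. At 3, 24 and 72 h, 0, 1 and 2 of 4 controls matched best with their own number. These values show no clear pairing and do not rule it out. With the replicate number as a block, 4230, 6189, 5654, 7427, 5641, 595 and 2765 genes and 7, 10, 15, 9 and 9 lists were called, and with the block within each time 4219, 6134, 5590, 7318 and 5497 genes. Without the doubted libraries the calls of the enterocyte list at 3 h (0.176), the goblet and MHC class II lists at 24 h (0.0599 and 0.0878), the Paneth and fatty acid lists at 72 h (0.125 and 0.0533) and the MHC class II list of the average (0.0634) ended. Of 13878 alternatives run on 641 values of named genes, 13543 stayed on the same side of the threshold, 311 fell below it, 24 newly passed it and 0 reversed while called. Depth limits what is said of Slit3, Robo1 and Robo2, with 22, 16 and 73 counts over all libraries, and of folds against controls at 0 counts, which are lower bounds.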

Other observations

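Further groups of interferon-linked genes, on lists chosen after their values were seen, so that their direction is not independent evidence, also rose with Slit3. Of 17 genes of MHC class I antigen presentation, 15, 16 and 16 rose at 3, 24 and 72 h, and 1 fell at 72 h (adjusted p with an estimated correlation 0.000575, 3.27e-05 and 4.53e-05). The peptide transporter Tap1 was at log2 changes of 2.71, 4.19 and 4.01, the immunoproteasome subunits Psmb9 and Psmb8 at 2.48, 4.96 and 4.57 and at 2.49, 5.85 and 4.97, and the light chain B2m at 0.65, 2.22 and 2.33. Of 11 nucleic acid sensors, 9, 10 and 10 rose and 1 fell at 72 h (4.37e-06, 7.56e-06 and 5.87e-06), among them the RNA-activated kinase Eif2ak2 at 1.97, 2.69 and 2.44, the editing enzyme Adar at 1.87, 2.62 and 2.60 and Tlr3 at 2.00, 3.32 and 2.52. Of these 11, Zbp1, Dhx58, Ddx58 and Ifih1 are also in the interferon list. Zbp1 and Aim2 are in the cell death list below as well.

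Of 20 genes of cell death, 11, 15 and 14 rose and 1 fell at each time (adjusted p with an estimated correlation 0.0186, 0.00268 and 0.0126), with Mlkl, the effector of necroptosis, at 1.42, 4.57 and 4.24, Gsdmd, which forms pores in pyroptosis, at 0.91, 2.58 and 2.03, Casp8 at 0.56, 0.93 and 0.63 and the death ligand Tnfsf10 at 1.69, 2.70 and 2.31. Of 25 enzymes of foreign compound metabolism, also listed after the values were seen, 0, 14 and 23 fell and 3, 3 and 1 rose (0.758, 0.416 and 0.0276). The list holds Ces1d and Ugt2b5, already named for their falls, so its p at 72 h is not an independent test. Gsta3 and Gstm1 are also in the NRF2 list. At 72 h Ces1d was at -2.56, Ces2g at -0.99, Cyp2c66 at -0.84 and Cyp2c65 at -0.74. Of 6 interferon receptor genes, 4, 3 and 2 rose and 0, 2 and 2 fell (0.0222, 0.471 and 0.887). Ifnlr1 was at 0.67, 0.56 and 0.46. Ifngr1, smaller in p than Ifnlr1 at 3 h, was at 0.39 at that time. The members that fell are not named here.

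The next list and its test were written after the control values were seen. Of 14 genes that respond to glucocorticoids, 8 fell and 1 rose in controls from 3 to 72 h, with a median log2 change of -0.425. A culture step shared by both arms, such as a change of medium, is a candidate explanation. The Slit3 libraries showed a median of -0.224 from 3 to 72 h, with 7 genes lower and 1 higher, and 7 lower in both arms. The bootstrap interval of this median, -1.041 to -0.017, comes from resampling the genes of the list. Genes are not independent replicates, so the interval does not measure the spread between libraries. Fkbp5 went from 199.1 to 35.53 CPM in controls and from 176.8 to 36.94 with Slit3, Hif3a changed by -1.86 and -1.56, Per1 by -1.02 and -0.95 and Tsc22d3 by -0.50 and -0.34, while Pdk4 went opposite ways, -1.80 and 0.81. The hypothesis rests on the same data that gave it, and the labels state nothing about medium changes.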
